A study of Mus musculus with 103 samples.

How the data were processed

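Macrophages that gather in the mouse peritoneum after injection of thioglycollate broth were taken from male C57BL/6 mice, cultured, starved of serum overnight and treated, per the labels' protocols. KLA (Kdo2-lipid A, the lipid A part of bacterial lipopolysaccharide and a pure TLR4 agonist) was given at 100 ng/ml, and GW3965, a synthetic agonist of the liver X receptors (LXR), at 1 µM. The labels describe 103 samples, of which 8 are analysed here: 6 libraries of poly(A) RNA and the ChIP-seq peak lists of SREBP1 and of LXR after GW3965. The bone marrow-derived macrophages, the knockdowns of Scap and Srebf1, the RNA after GW3965 or desmosterol and the other ChIP-seq samples of the series are not analysed here.

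The RNA values are RPKM (reads per kilobase of transcript, scaled to library size), as deposited by the authors in 1 table of 33022 transcripts with 24014 gene symbols on mouse build mm9. Bowtie 0.12.7, STAR, HOMER and build mm9 are named in the submitters' processing notes, without saying which files each was used for. Whether reads were assigned by strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and genes with close copies elsewhere in the genome are uncertain. Hmgcs1, an abundant enzyme of cholesterol synthesis in most cells, is listed at 0 in all 6 libraries, so a 0 in this table can mean that no read was assigned and not that the RNA was absent.

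The peak lists were made with HOMER, per the file headers, which give a false discovery rate of 0.001, a minimum of 4-fold over the input and over the surrounding 10000 bases, and a Poisson threshold of 1.00e-04 over the surrounding bases. The normalised tag count of a peak is a signal scaled by the authors to 10000000 tags per library. The fold over the input and over the surrounding bases is a ratio computed by the authors' peak caller, and the peak score is the authors' own value, used here only to rank or filter peaks within a list. SREBP1 peaks of 194 bases were called from 24395376 tags and LXR peaks of 184 bases from 7501248 tags, per the file headers. The chromatin was fixed with disuccinimidyl glutarate and formaldehyde and each factor was precipitated with several antibodies, per the labels' protocols. The SREBP1 tag directory is named as a combined one with an input from untreated cells, and each list has 1 header, so no replicate of a peak can be compared. Which samples were combined for SREBP1 is not known.

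Some labels and headers differ. The LXR sample is titled as treated with GW3965 while its treatment characteristic reads as a control. The LXR header names 5 h of GW3965 and an input from cells given KLA for 24 h, and the SREBP1 label gives 18 h of GW3965. The samples were used under their titles.

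From each RPKM value the number of reads was recovered as value × transcript length × a library total, the total being the one at which values came out as whole reads. Between 99.7% and 99.9% of the values of a library were whole within 0.01 read. The totals were 2205191 (untreated, control for 1 to 12 h), 2399934 (KLA 1 h), 2372817 (6 h), 2447145 (12 h), 2587521 (untreated, control for 24 h) and 2674829 (KLA 24 h). At these depths 1 read in a transcript of 1 kb is worth 0.374 to 0.453 RPKM. Intervals on a ratio of RPKM are 95% exact conditional binomial (Clopper-Pearson) intervals on the recovered reads. They cover counting error alone, as do the floors. Where 1 library had 0 reads, the ratio was set against a floor of 3 reads and is written as a bound.

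Each gene was represented by the transcript of highest mean RPKM, and 10605 genes with RPKM of at least 1 in 2 libraries were tested. Changes are log2 ratios of RPKM + 1, which understate the change of weakly expressed genes, and counts of genes at least 2-fold higher or lower use this scale. Folds given for single genes are plain ratios of RPKM. The analysis was planned with limma across replicated groups, with set tests, knockdown and ligand comparisons. As only 1 library a side was analysed, the rule fixed in advance for such comparisons was used: log2 ratios, no p-values, and, for a gene list, the percentile of its median among 10000 random lists of the same size matched on mean expression in 20 bins, called outside below percentile 2.5 or above percentile 97.5. KLA at 1, 6 and 12 h was compared with 1 untreated library and KLA at 24 h with the other. KLA 24 h against KLA 6 h is the difference between the 2 log2 ratios. The 2 untreated libraries were compared with each other as background.

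The 16 gene lists, with 276 members of which 1 is missing from the table, were fixed before the data were examined: cholesterol synthesis and uptake, fatty acid synthesis and desaturation, LXR targets, inflammatory cytokines and NF-κB targets, interferon response, fatty acid oxidation and storage, glycolysis, TCA cycle, cell cycle, macrophage identity, alternative activation, and markers of neutrophils, lymphocytes, dendritic cells, mast cells with eosinophils, and stromal with mesothelial cells. Named genes are 22 genes fixed in advance, the 8 highest and 8 lowest log2 ratios among genes with RPKM of at least 5 in either library, and members of the lists. The same rule restricted to transcripts of at least 200 bases was added after the data were seen, because many of the lowest ratios came from small RNA genes with few reads. Some of the fixed genes and list members are counted in the totals but not reported here singly. List members used as examples were chosen after their values were seen. Named peaks are the 10 of highest score in each list and those within 10 kb of the fixed genes. A peak has the position that its file gives, and its place relative to genes comes from the transcript positions in the RPKM table. The reference annotation at hand is of build GRCm38, where 675 of 32586 shared transcripts have the same start or end, and it was not used for positions. Exons, introns and motifs were not analysed here.

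Peaks overlapped when they shared at least 1 base, and 1000 random shifts of the SREBP1 peaks along their chromosomes gave the overlap without alignment. A gene had a peak when one lay within 10 kb of its start site, and shares of a gene set were compared with 10000 matched random sets.

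On simulated reads of the 10605 genes, genes raised or lowered 4-fold came out beyond 2-fold in 90% (KLA 1 h), 88% (6 h), 85% (12 h) and 92% (24 h) of 100 genes each, and unchanged genes in 1.41%, 1.67%, 1.20% and 1.62%. Only counting error was simulated, so these shares leave out differences between libraries. Between the 2 untreated libraries 182 of the 10605 genes were at least 2-fold higher and 257 lower, 78 and 157 of them beyond counting error. In simulation with values drawn independently for each gene, 5 of 100 unmoved lists lay outside the percentiles. A planted peak overlap of 30% was recovered as 30%. Both outcomes were set by the design of the simulation and check the calculation alone. How often real lists lie outside without KLA is not given by them. Between the 2 untreated libraries the cholesterol and interferon lists lay at percentiles 99.89 and 99.99. Alternatives were a pseudocount of 0.1 or 3, no filter, RPKM of at least 5 in 2 libraries, rescaling of libraries by the median of ratios, sums over all transcripts of a gene, other peak overlaps and windows, and, chosen after the data were seen, the other untreated library as control, random sets matched on expression in the untreated libraries, leaving out transcripts under 200 bases, and leaving out the 7 SREBP1 peaks of highest score. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.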

Results

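RNA of thioglycollate-elicited peritoneal macrophages was measured in 6 libraries, 1 per condition: untreated cells that served as the control for 1 to 12 h, cells given KLA (a TLR4 agonist) for 1, 6 or 12 h, a separate untreated library for 24 h, and cells given KLA for 24 h. There were no replicates, so every difference below is between 2 libraries and no p-value is given. The libraries were shallow, with 2205191 to 2674829 reads in total and 1883937 to 2309724 reads in genes, and 9266 to 10172 genes reached an RPKM of 1. A transcript of 1 kb with no read could have had an RPKM of up to 1.12 to 1.36 (3 reads). The most abundant RNA was that of Gpnmb or Fth1, with 2.14% to 3.28% of the reads in genes, and the 10 most abundant genes held 13.8% to 18.7%. Binding of SREBP1, the transcription factor encoded by Srebf1 that drives genes of lipid synthesis, and of the oxysterol receptor LXR was given as 1 peak list each from macrophages treated with the LXR agonist GW3965. The series was described as a study of lipid metabolism and inflammation over time, and the comparisons below ask how genes of both kinds stood after each time of KLA, and where the 2 lipid regulators bound.

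After 1 h of KLA, RNAs of cytokines and chemokines were far higher than in untreated cells. Tnf, the gene of tumour necrosis factor (NM_001278601, chr17 35336312–35338952, mm9), stood at 18.9 RPKM without KLA and at 5276 with it, a 279-fold difference (95% counting interval 219 to 360). Against the untreated 24 h library, where Tnf was lower, the fold was 1684 (985 to 3164). Tnfsf9, the gene of the 4-1BB ligand, was 486-fold higher (246 to 1126), and the neutrophil chemoattractant Cxcl2 (chr5 91332925–91334964) was 323-fold higher (228 to 476). Il1b, the gene of interleukin-1β (chr2 129190316–129196856), went from 6.84 to 2095 RPKM, and Nfkbiz, Cxcl1, Ccl4 and Irg1 were 245-, 199-, 133- and 129-fold higher. The folds of Tnfsf9, Cxcl2, Il1b, Cxcl1 and Ccl4 were 2280, 735, 799, 995 and 275 against the untreated 24 h library. Gadd45g, a growth arrest and stress gene, was 7.79-fold lower (5.34 to 11.7), the cannabinoid receptor gene Cnr2 6.42-fold lower (3.98 to 10.9) and the ubiquitin ligase gene Fbxo32 4.43-fold lower (3.67 to 5.39). The 8 lowest ratios of all came from small RNA genes with 2 to 4 reads and are not given singly.

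Of the 39 inflammatory genes tested, 34 were at least 2-fold higher at 1 h and none was 2-fold lower. Their median log2 ratio was 3.03 (3.05 with the genes without control reads set at their bound), or 3.19 above the median of all genes, and lay above all 10000 matched random lists. Il23a, a subunit of interleukin-23, was at 76.1 RPKM at 1 h against 0.334 (1 read) in untreated cells and 0.621 at 6 h. Nfkbia, the gene of the NF-κB inhibitor IκBα, was at 1574 RPKM against 26.4. The interferon response list had a median of 0.28, above all random lists, with 13 of 31 genes at least 2-fold higher and 1 lower. Ifnb1 itself had 30.3 RPKM at 1 h and no read in untreated cells, at least 17.2-fold higher, while the antiviral gene Mx1 was at 0.464 against 0.673 RPKM. Among lipid genes, Insig1, whose protein holds SREBP in the endoplasmic reticulum (NM_153526, chr5 28397952–28405202), was 2.51-fold higher (2.15 to 2.93). Cholesterol (median 0.10 above that of all genes, percentile 89.05), fatty acid synthesis (−0.05, percentile 33.84) and LXR target lists (−0.10, percentile 10.52) lay inside the central 95% of random lists at 1 h. In all, 387 of 10605 genes were at least 2-fold higher and 434 lower, 304 and 325 of them beyond counting error. After rescaling the libraries the counts were 437 and 274. The median log2 ratio of all genes was −0.16 at 1 h, −0.46 at 6 h, −0.32 at 12 h and −0.09 at 24 h, and list medians given relative to all genes take this shift out.

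After 6 h of KLA, interferon-induced genes as well as cytokine genes were far higher than in untreated cells. Ifit2, an antiviral interferon-induced gene (NM_008332, chr19 34625184–34651024), stood at 1346 RPKM against 1.03 in untreated cells, 1302-fold higher (686 to 2848), Ifit1 was 942-fold higher (496 to 2060) and Cmpk2 723-fold higher (445 to 1265). The chemokine gene Cxcl10 reached 3643 RPKM (441-fold, 286 to 723), Il1b 4048 RPKM (592-fold, 383 to 969) and Irg1, which encodes the enzyme that makes itaconate, 2323 RPKM (414-fold, 293 to 606). Il6 (554 RPKM) and the guanylate-binding protein gene Gbp5 (480 RPKM) had 1 read each in untreated cells, with ratios of 1327 (238 to 52455) and 3197 (573 to 126310). Against the untreated 24 h library the fold was 179 for Gbp5, 550 for Ifit2, 432 for Ifit1 and 1543 for Il1b. Nos2, the inducible nitric oxide synthase, had 2 reads without KLA and 601 with it (279-fold, 77.0 to 2311), or 164-fold against the untreated 24 h library. Tnf was at 1648 RPKM, 87.0-fold above its own untreated library (68.4 to 112) and 526-fold above the other.

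The 8 lowest ratios at 6 h included the chemokine receptor Cxcr4 (chr1 130484776–130488876), at 2.79 against 124 RPKM (44.5-fold lower, 25.2 to 86.7), Tsc22d3, a glucocorticoid-induced gene, 27.9-fold lower (16.4 to 51.5), and Tcp11l2, at least 43.0-fold lower. The uncharacterised gene 1810011H11Rik was at least 20.1-fold lower, and the other 4 were microRNA genes with 3 to 7 reads. Ypel3 was 19.1-fold lower (9.83 to 42.6) and the sialyltransferase gene St6gal1 25.2-fold lower (14.2 to 49.3). All 31 interferon response genes were at least 2-fold higher, with a median of 5.24 (5.29 at the bound) that lay 5.70 above that of all genes. Rsad2, the gene of the antiviral protein viperin, was at 4216 against 12.7 RPKM, Mx1 at 416 and Irf7 at 699 against 17.5. Of the inflammatory genes 36 of 39 were at least 2-fold higher (median 4.69, also at the bound). Both medians lay above all random lists.

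Fatty acid synthesis genes were lower by different amounts at 6 h, with 15 of 16 log2 ratios below 0 and 1 above. The median of all genes was also below 0, at −0.46. Fads1, the delta-5 desaturase (NM_146094, chr19 10257378–10271362), was 6.17-fold lower (4.33 to 9.00) at 4.51 against 27.8 RPKM, the elongase Elovl5 3.74-fold lower (2.81 to 5.03) and the stearoyl-CoA desaturase Scd2 (chr19 44368166–44381352) 3.38-fold lower (2.67 to 4.30), or 6.60-fold against the untreated 24 h library. Fasn, the fatty acid synthase, was 1.64-fold lower (1.18 to 2.30). Scd1, Fads2 and Elovl6 stood at ratios of 0.654 (0.344 to 1.22), 0.664 (0.264 to 1.61) and 0.636 (0.289 to 1.36), not distinguishable from 1 at this depth (Scd1 was 4.63-fold lower than the other untreated library), and the elongation reductase Hsd17b12 was 1.33-fold higher (1.14 to 1.55). Of the 16 fatty acid synthesis genes 5 were at least 2-fold lower and none higher, and the median of −0.65, 0.20 below that of all genes, was at percentile 17.31. In the cholesterol list 1 of 22 genes was 2-fold lower and none higher (median −0.34, or 0.10 after rescaling, 0.12 above that of all genes, percentile 70.85). The squalene epoxidase Sqle was 1.49-fold lower (1.22 to 1.82). Dhcr7, which makes cholesterol from its direct precursor, was at 4.19 against 19.8 RPKM. The LXR targets had 1 gene higher and 4 lower of 14 (median −0.59, percentile 21.17), and their median was 0.15 against the other untreated library. The cholesterol exporter Abca1 (chr4 53043661–53172767) was 2.28-fold higher (1.85 to 2.81) than its own control and at a ratio of 1.02 (0.874 to 1.19) to the other untreated library. Abcg1 (chr17 31194639–31254926) was 2.75-fold lower (2.36 to 3.21). At 6 h 992 genes were at least 2-fold higher and 2375 lower (894 and 2197 beyond counting error), so that 29.5% of them were higher. After rescaling the counts were 1417 and 1256, or 53.0% higher.

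After 12 h of KLA the interferon response list had its highest median log2 ratio over the times of KLA. That median was 5.92 (6.13 at the bound, 6.25 above all genes), with 30 of 31 genes at least 2-fold higher. The mean of the list was higher at 6 h (5.75) than at 12 h (5.60). With a pseudocount of 3 the median was higher at 24 h (4.82) than at 12 h (4.79). The chemokine gene Ccl5 (NM_013653, chr11 83339281–83344020) was at 11289 against 21.4 RPKM (528-fold, 357 to 816), Isg15, a ubiquitin-like modifier, 440-fold higher (232 to 964) and Ms4a4c at least 699-fold higher, from no read to 552 RPKM. Irf7, the interferon regulatory factor, was at 1333 RPKM. Ifit2 (752-fold), Ifit1 (534-fold), Il1b (363-fold) and Irg1 (326-fold) were again far above untreated cells, and of the inflammatory genes 35 of 39 were at least 2-fold higher (median 4.34, also at the bound). Both lists lay above all random lists. Saa3, an acute-phase gene that stood at 502 against 556 RPKM at 1 h, was at 2824 RPKM, and Tnf was at 1160 RPKM, 61.2-fold above its own untreated library (48.1 to 79.2) and 370-fold above the other. Ifit2, Ifit1 and Il1b were 317-, 245- and 947-fold above the untreated 24 h library. The kinase gene Matk was 46.8-fold lower (19.8 to 146), the extracellular matrix gene Mamdc2 20.5-fold lower (16.7 to 25.5) and Pparg, a nuclear receptor that drives lipid uptake and storage (chr6 115372084–115440419), 23.1-fold lower (13.0 to 45.3). Cmbl, a hydrolase gene, was at least 18.9-fold lower, and Susd3 was at 0.358 RPKM (1 read) against 29.8.

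The cholesterol list was high relative to all genes at 12 h, with a median of 0.14 at percentile 99.3, 17 of 22 genes above the median of all genes and none 2-fold higher. Against the other untreated library the plain list median, not taken relative to all genes, was −0.18 instead of 0.14. Of the fatty acid synthesis genes 1 was 2-fold higher and 3 lower of 16 (median −0.42, percentile 27.71). Fads1 was 2.83-fold lower (2.19 to 3.70) and Elovl5 3.74-fold lower (2.82 to 5.01), while Hsd17b12 was at 125 against 72.5 RPKM. The LXR targets had a median of −0.66 at percentile 2.98, inside the central 95%, with 3 of 14 lower and 1 higher, and a median of 0.045 against the other untreated library. Abca1 was 2.74-fold higher (2.24 to 3.36), or 1.23-fold (1.06 to 1.42) against the other untreated library, and Abcg1 3.05-fold lower (2.61 to 3.58). In all 942 genes were at least 2-fold higher and 1730 lower (849 and 1573 beyond counting error, 35.3% higher), and 1213 and 1050 after rescaling (53.6% higher).

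**Figure D1:**
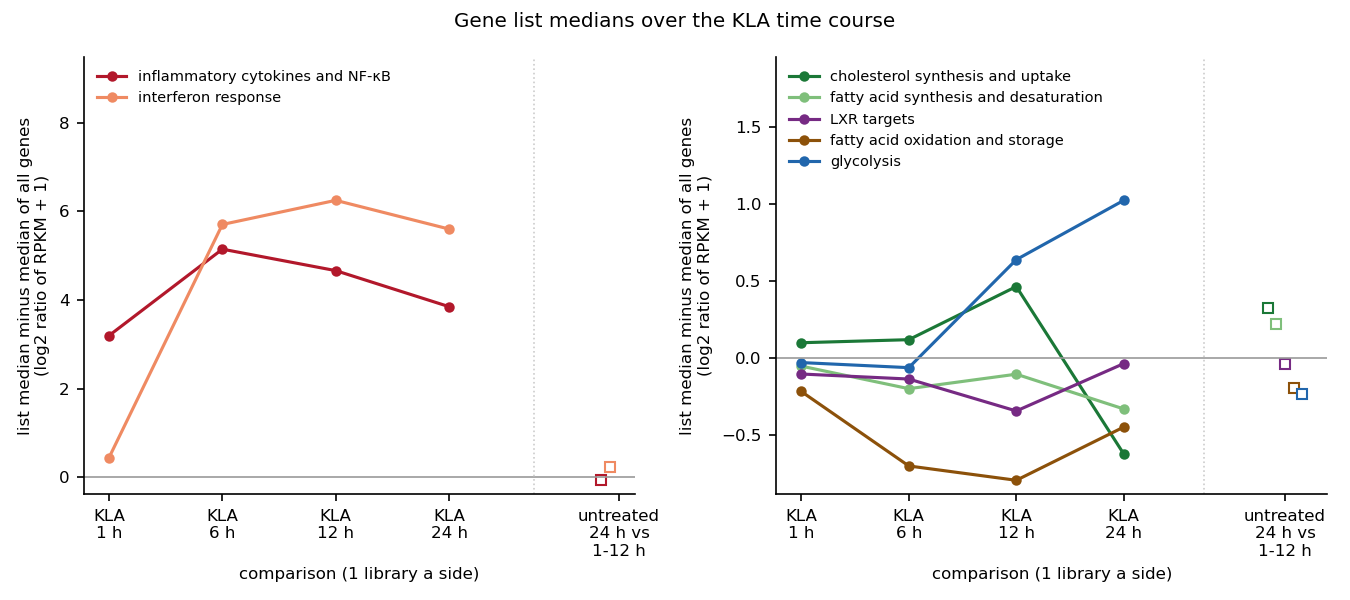
Median log2 ratio (RPKM + 1) of 7 gene lists minus the median of all genes (y axis) after 1, 6, 12 and 24 h of KLA and for the untreated pair (open squares), with 1 library a side. The inflammatory and interferon lists (left panel) reach 5.14 and 6.25, and the metabolic lists (right panel) stay between −0.79 and 1.03, with the cholesterol list at 0.47 at 12 h and −0.62 at 24 h, where a different untreated library is the control.

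After 24 h of KLA, genes of cholesterol synthesis were lower than in the untreated 24 h library, while inflammatory and interferon genes stayed high. Sqle (NM_009270, chr15 59146647–59162748) was at 25.3 against 57.7 RPKM, 2.28-fold lower (1.91 to 2.72), the lanosterol demethylase Cyp51 (chr5 4080674–4104697) 2.06-fold lower (1.78 to 2.38) and the sterol desaturase Sc5d 2.94-fold lower (2.50 to 3.46). Against the other untreated library, at 38.8, 36.8 and 63.3 RPKM, these genes were also lower, but less than 2-fold. With KLA Cyp51 and Sc5d were at 24.3 and 34.4 RPKM. Of the 22 cholesterol genes 6 were at least 2-fold lower, none was higher and 19 lay below the median of all genes. The list median was −0.71, 0.62 below that of all genes and at percentile 0.01 of matched random lists. Insig1 was 1.41-fold lower (1.18 to 1.67). The regulator genes Srebf2 and Scap were 1.56-fold (1.32 to 1.84) and 1.80-fold lower (1.26 to 2.60), and Srebf1 was at a ratio of 1.19 (0.907 to 1.57), or 0.762 (0.591 to 0.982) against the other untreated library.

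Fatty acid synthesis genes had a median of −0.42 at 24 h, 0.33 below that of all genes and at percentile 4.48, inside the central 95%. Of 16 genes 1 was at least 2-fold lower, none higher and 13 below the median of all genes. Fads1 was 2.44-fold lower (1.92 to 3.11), Elovl5 1.96-fold lower (1.64 to 2.37), Fasn 1.91-fold lower (1.43 to 2.58) and Elovl6 3.40-fold lower (1.41 to 9.37, on 7 reads with KLA). Scd1 and Fads2 stood at ratios of 0.917 (0.681 to 1.23) and 0.760 (0.312 to 1.80), not distinguishable from 1 at this depth, but Scd1 was 2.78-fold higher (1.79 to 4.44) than the other untreated library. Scd2 was 1.17-fold lower (1.05 to 1.31) than the untreated 24 h library and on the log2 scale 0.71 higher than the other untreated library. Of the 14 LXR targets 2 were at least 2-fold higher than in the untreated 24 h library and none lower (median −0.12, percentile 34.46, and a median of −0.46 against the other untreated library). These counts depend on the control. Apoc2, higher at 9.78 against 3.73 RPKM, stood at 9.37 RPKM in the other untreated library. Pltp and Cd5l, at 55.5 and 17.1 RPKM with KLA, were more than 2-fold below that library (230 and 77.1). Abca1 was at 29.8 against 12.9 RPKM (2.31-fold higher, 2.03 to 2.63, and 5.15-fold against the other untreated library), Abcg1 1.96-fold lower (1.74 to 2.21) and the ubiquitin ligase gene Mylip 1.93-fold lower (1.23 to 3.10). Apoe, the apolipoprotein of macrophages, was at 1533 against 2826 RPKM, and stood at 5741 RPKM in the other untreated library.

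**Figure D2:**
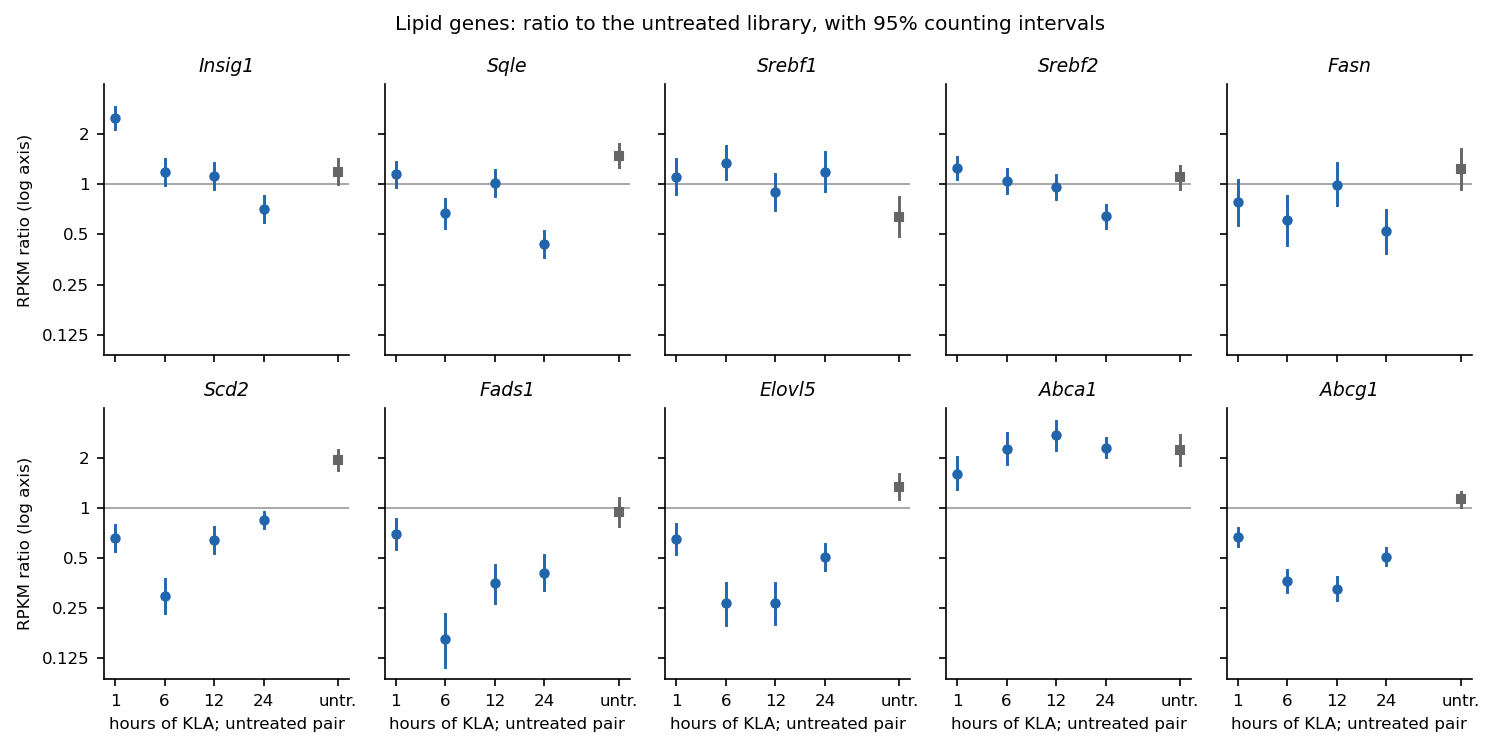
Ratio of RPKM with KLA to RPKM without (log axis) for 10 lipid genes by hours of KLA, with the untreated pair as a grey square and bars for 95% counting intervals, 1 library a side. Abca1 lies above 1 at all 4 times (1.61, 2.28, 2.74 and 2.31), but against the other untreated library its ratio was 0.723 at 1 h, 1.02 at 6 h and 1.23 at 12 h. Abcg1 lies below 1, Fads1 is lowest at 6 h and Sqle at 24 h.

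The inflammatory and interferon lists both lay above all random lists at 24 h. Of 39 inflammatory genes 34 were at least 2-fold higher (median 3.76, also at the bound), and of 31 interferon genes all 31 (median 5.51, also at the bound). Ccl5 was 360-fold higher (249 to 542), Il1b 305-fold (161 to 668), Cfb, a component of the alternative complement pathway, 243-fold (176 to 345), the formyl peptide receptor Fpr2 279-fold (119 to 862) and Irg1 236-fold (177 to 322). Isg15 was 199-fold higher (116 to 374), AW112010 274-fold (177 to 449), and Ms4a4c was at 583 RPKM against 3 reads (866-fold, 296 to 4201). Nos2 (chr11 78734361–78773626) had 4 reads without and 1554 with KLA (376-fold, 146 to 1381), and Lcn2, an iron-sequestering protein, was at 136 against 0.454 RPKM (1 read). Tnf was at 639 against 3.13 RPKM, 204-fold higher (119 to 384), but 33.7-fold (26.5 to 43.7) against the other untreated library, where it stood at 18.9 RPKM. Il1b and Fpr2 were 117-fold and 1190-fold above that library, and Nos2 641-fold. Il12b, the p40 chain of interleukin-12, was at 7.48 RPKM after 72.0 at 6 h. Mamdc2 (chr19 23377099–23522812) was 63.4-fold lower (45.8 to 90.2), Fam198b 55.8-fold (33.6 to 100), the cell cycle inhibitor gene Cdkn1c (chr7 150644244–150646955) 24.1-fold (19.9 to 29.4), Bex1 45.0-fold (12.1 to 377, on 2 reads with KLA), Cd300lb 17.7-fold (14.0 to 22.8) and Pparg 17.8-fold lower (10.9 to 31.0). Fam198b and Cdkn1c were 33.6-fold and 13.6-fold lower than the other untreated library. Beside these groups, the neutrophil marker S100a8 was at 118 against 45.5 RPKM (2.59-fold, 1.83 to 3.71) and the fibroblast marker Dcn at 104 against 59.5 (1.75-fold, 1.51 to 2.04). In all 1058 genes were at least 2-fold higher and 1122 lower, 962 and 1023 beyond counting error.

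The changes at 6 h and 24 h were compared as the difference between the log2 ratios to each time's own untreated library. In 1793 genes the log2 ratio was at least 1 higher at 24 h than at 6 h and in 559 at least 1 lower, with a median over all genes of 0.32. After rescaling the counts were 945 and 1012, so which way this balance tips rests on the scaling. Of the genes at least 2-fold higher, 642 were so at both times, where independent lists would share 99.0, and 740 were lower at both, where independent lists would share 251. Another 20 genes were higher at 6 h and lower at 24 h and 33 the reverse. Il12b was at 72.0 RPKM at 6 h and 7.48 at 24 h, Cxcl10 441-fold and 150-fold (99.8 to 237) above its controls, and Saa3 at 873 and 4409 RPKM. The relative cholesterol median was 0.12 at 6 h and −0.62 at 24 h, and this difference between times was not tested.

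The 2 untreated libraries give the background of these comparisons. Between them 182 genes were at least 2-fold higher and 257 lower in the 24 h library (78 and 157 beyond counting error), with a median log2 ratio of 0.02 over all genes. The 8 highest and 8 lowest ratios came from small RNA genes with 2 to 5 reads. Lipid genes were among those that differed. Scd1 was 3.03-fold higher (1.96 to 4.83), Abca1 2.23-fold (1.82 to 2.75), Scd2 1.96-fold (1.70 to 2.25) and Sqle 1.49-fold (1.26 to 1.75) in the untreated 24 h library. The cholesterol list lay at percentile 99.89 (median 0.35), the interferon list at percentile 99.99 (0.26) and the fatty acid synthesis list at percentile 96.18 (0.24), while the inflammatory list (−0.05) and LXR targets (−0.02) were at percentiles 69.3 and 51.85. Tnf was 6.05-fold lower (3.31 to 11.9), the scavenger receptor Marco 6.37-fold lower (2.81 to 16.9), Cd5l 4.32-fold lower (3.43 to 5.48), and the B cell chemokine Cxcl13 2.68-fold higher (2.16 to 3.35). Abca1 at 1 h of KLA, 1.61-fold above its own control (1.30 to 2.01), lay 0.43 below the untreated 24 h library on the log2 scale. Against that library Ypel3 was 12.2-fold lower at 6 h and Matk 26.3-fold and Susd3 49.2-fold lower at 12 h.

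SREBP1 and LXR peaks of GW3965-treated macrophages lay near several lipid genes. The SREBP1 list held 13984 peaks, 39.5% of them within 1 kb of an annotated start site (95% interval 38.7 to 40.3), and the LXR list 40660 peaks, 17.1% within 1 kb (16.7 to 17.5). Among the 100 highest scores of each list the order was the opposite, with 43% of SREBP1 and 84% of LXR peaks within 1 kb. The lists differ in depth and enrichment, since 1.75% of SREBP1 tags and 17.85% of LXR tags fell in peaks, per the file headers, and their lengths are not compared. SREBP1 peaks near the fixed genes had scores from 77 down to near the list median of 10. The peak of Srebf2 (chr15 81977450–81977644, 152 bases upstream of the start site) had an authors' score of 77, a peak by Scd2 (chr19 44368328–44368522) 53 and one by Insig1 (chr5 28398489–28398683) 50, while those by Elovl6, Fads2 and Sqle had 17, 13 and 11. High-scoring LXR peaks, with a list median of 12, lay inside Srebf1 (chr11 60024022–60024206, score 260), at Mylip (chr13 45486973–45487157, 250), Scd2 (chr19 44358652–44358836, 234), Abcg1 (chr17 31195756–31195940, 209), Fasn (chr11 120685986–120686170, 217 bases upstream, 178) and Abca1 (chr4 53172744–53172928, 69 bases upstream, 148). Of the 22 fixed genes, 19 had a SREBP1 peak within 10 kb (not Scap, Il6 or Nos2) and 21 an LXR peak (not Il6). The peaks by Tnf, Il1b and Cxcl10 had SREBP1 scores of 9, 15 and 10.

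The SREBP1 peak of highest score (336) lay 194 bases upstream of Pgk1, a glycolytic enzyme gene (chrX 103382148–103382342), and overlapped an LXR peak. The next 6 all lay inside the transcribed region of Vdr, the vitamin D receptor gene, with scores of 221 (chr15 97687879–97688073), 153, 150, 132, 126 and 124, and none overlapped an LXR peak. Vdr RNA was at 0 to 0.266 RPKM in the 6 libraries, and the 6 SREBP1 peaks that flank the gene within 200 kb had scores of up to 23. Ranks 8 to 10 were peaks nearest to Axin2 (chr11 108873052–108873246, 91), Snrnp35 (chr5 124942650–124942844, 89) and Idh1, a cytosolic source of NADPH (chr1 65233037–65233231, 88).

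**Figure D3:**
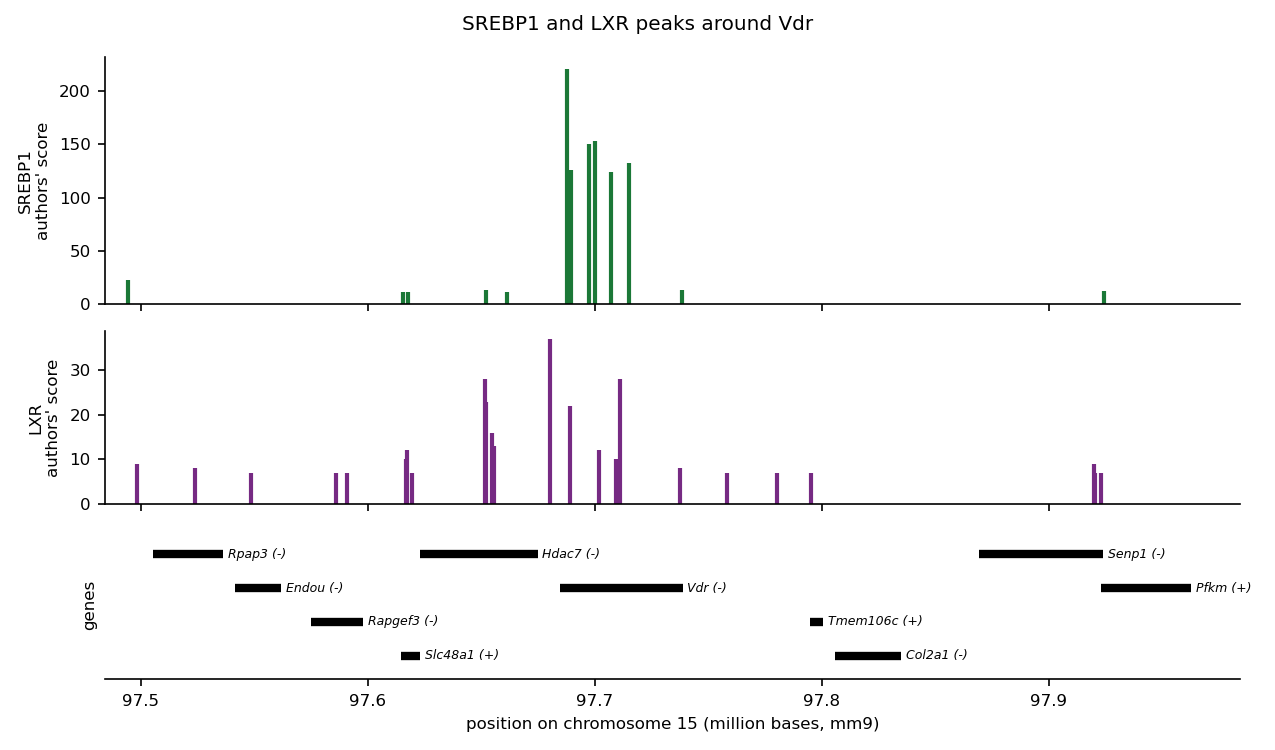
Authors' score of SREBP1 and LXR peaks (y axis) by position on chromosome 15 (mm9) around Vdr, with genes and their strands drawn to scale. The 6 high SREBP1 peaks (scores 124 to 221) lie inside the transcribed region of Vdr and the flanking ones reach 23.

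The 10 highest LXR peaks all lay within 1 kb of a start site. Taf15 (chr11 83286327–83286511, 305) and Rita1 (chr5 121062702–121062886, 305) led, followed by Cdipt (294), Cd3eap (293), Lsg1 (290), Rpl19 (289), Mgea5, Rab28 and Hexim1 (285 each) and Eif3b (284), of which the peak at Rab28 alone overlapped a SREBP1 peak.

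SREBP1 and LXR peaks coincided far more often than shifted peaks did. Of the SREBP1 peaks 3808, or 27.2% (26.5 to 28.0), shared at least 1 base with an LXR peak, while shifted SREBP1 peaks did so in 0.629% on average and 0.930% at most over 1000 shifts. Shifting does not keep peaks in open chromatin, so this comparison does not separate shared binding from shared open regions. The overlap was 22.7% (21.6 to 23.8) within 1 kb of a start site and 30.2% (29.2 to 31.2) farther away, and went from 17.6% (15.6 to 19.7) in the lowest of 10 groups of SREBP1 score to 45.6% (42.9 to 48.2) in the highest. A peak inside Srebf1 (chr11 60023880–60024074) overlapped an LXR peak, and that of Srebf2 did not. Of the LXR peaks 9.36% (9.08 to 9.65) overlapped a SREBP1 peak. With an overlap of at least 50% of each peak the SREBP1 share was 15.1%.

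**Figure D4:**
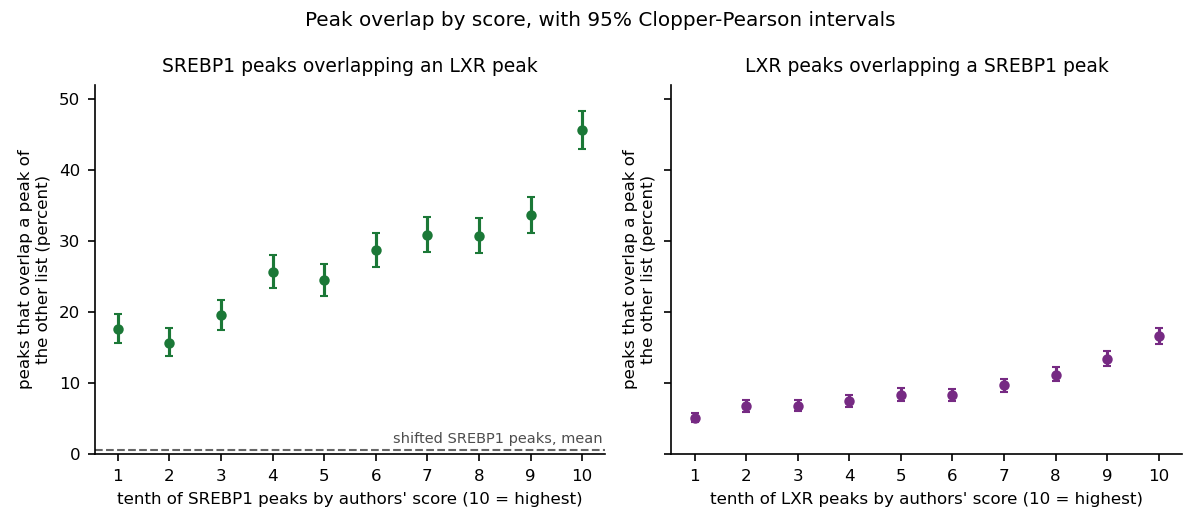
Percent of peaks that overlap the other list (y axis) by group of the authors' score (x axis, group 10 highest) for SREBP1 and LXR, with 95% Clopper-Pearson bars and a dashed line for the mean of shifted SREBP1 peaks (0.629%). The SREBP1 share goes from 17.6% to 45.6% and the LXR share from 5.12% to 16.6%.

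Genes of cholesterol synthesis had SREBP1 peaks near their start sites more often than matched genes, while the result for inflammatory and interferon genes depended on the matching. A SREBP1 peak lay within 10 kb of 20 of 22 cholesterol genes, where random lists matched on expression had 63.8% (percentile 99.8), 13 of 16 fatty acid synthesis genes (60.3%, percentile 95.8) and 13 of 14 LXR targets (65.8%, percentile 98.7). It was 18 of 39 for inflammatory genes (67.2%, percentile 0.28) and 15 of 31 for interferon genes (68.6%, percentile 0.935). The mean expression used here includes the KLA libraries. With random lists matched on expression in the untreated libraries, chosen after the results were seen, the inflammatory list was at percentile 13.3 (54.8% in random lists) and the interferon list at 32.5 (52.5%), and the cholesterol list at 99.7 and LXR targets at 98.6. LXR peaks lay by 14 of 14 LXR targets (83.9%, percentile 95.8), 16 of 22 cholesterol genes (80.8%, percentile 16.9), 14 of 16 fatty acid synthesis genes, 32 of 39 inflammatory genes (percentile 17.2) and 23 of 31 interferon genes (89.5%, percentile 0.795, or 68.8 with untreated matching). Of the genes at least 2-fold higher after 6 h and 24 h of KLA, 53.1% (50.0 to 56.3) and 53.3% (50.2 to 56.3) had a SREBP1 peak within 10 kb, below all random sets matched on mean expression (62.8% on average at both times). When the random sets were matched on expression in untreated cells they had 54.3% and 54.8%, with the observed shares at percentiles 19.6 and 13.1. Of the lower genes 63.8% and 59.6% had a SREBP1 peak (percentiles 100 and 44.5, or 90.3 and 0.71 with untreated matching), so that each time lay outside the central 95% with 1 matching only. LXR peaks lay by 78.3% and 78.5% of the higher genes (80.1% in random sets, percentiles 6.70 and 9.34), above all random sets when these were matched on untreated expression (71.8% at both times). They lay by 82.2% and 81.8% of the lower genes (75.8%, above all random sets, and percentiles 100 and 98.5 with untreated matching). Of all 10605 genes 60.2% had a SREBP1 peak within 10 kb, 76.1% an LXR peak and 5309 both, where independent lists would share 4857.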

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

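The tests of the cholesterol genes in this part were chosen only after the result was seen. The values of 1 list and 2 genes went opposite ways at different times of KLA. The cholesterol list differed by 0.86 on the log2 scale between 12 h (0.14) and 24 h (−0.71). Srebf2, the gene of the main regulator of cholesterol synthesis, differed by 0.93 between 1 h (0.32) and 24 h (−0.61), and Insig1, which holds SREBP back, by 1.78 between 1 h (1.30) and 24 h (−0.48). None of these differences between times was tested, since each time has 1 library and 24 h has its own untreated library.

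For the lower cholesterol genes at 24 h, the tables argue against the untreated 24 h library alone, because against the other untreated library the list median was −0.53, at percentile 0.45 of its matched random lists (central 95% from −0.40 to 0.29). They argue against the scaling of the RPKM values too, since the median was −0.64 after rescaling. The plain list median at 12 h does depend on the control and was −0.18 against the other untreated library. A later fall of cholesterol synthesis genes with time of KLA may account for the pattern and stays a hypothesis, as does a property of the 1 library of KLA 24 h, which was not tested.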

How the results depend on the processing

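The other untreated library as control, random sets matched on untreated expression, the set without transcripts under 200 bases, the set without the 7 highest SREBP1 peaks, the windows for genes with peaks and the alternatives for 1 h, 12 h and the untreated pair were chosen only after the data were seen. No paired analysis was possible because each condition had 1 library. For the same reason the fits without set terms, over single sets, leaving out a library, with an siRNA block or with an estimated correlation, and the peak tests of GW3965 and knockdown genes, were not run. Called list medians kept their sign in 18 of 18 cases under each setting (17 of 17 with RPKM of at least 5) except the other untreated library (17 of 18), and called fixed genes in 62 of 62 (58 of 58) except there (60 of 62). Among the 258 main values recomputed, 197 stayed within their limits, 60 moved and 1 reversed. For fixed genes 82 of 692 values moved and 2 reversed. At this depth a gene of few reads has a wide interval, which no setting narrows. Except where named, the cause of a move was not tested.

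With a pseudocount of 0.1, which weights weak genes more by construction, 880 genes were lower at 1 h (434 as reported), and 506 higher and 496 lower between the untreated libraries (182 and 257). The inflammatory median was 4.34, 5.52, 4.65 and 4.26 at 1, 6, 12 and 24 h (3.03, 4.69, 4.34 and 3.76), and the interferon median 6.41, 6.56 and 5.88 at 6, 12 and 24 h (5.24, 5.92 and 5.51). With a pseudocount of 3, which shrinks them, 127, 1366, 920 and 694 genes were lower at 1, 6, 12 and 24 h (434, 2375, 1730 and 1122), 986 higher and 338 lower at 24 h than at 6 h (1793 and 559), and 76 higher and 116 lower between the untreated libraries. The inflammatory median was 2.68, 4.29 and 3.53 at 1, 6 and 12 h, the interferon median 4.59, 4.79 and 4.82 at 6, 12 and 24 h, and the fatty acid synthesis median −0.38 at 6 h (−0.65).

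With RPKM of at least 5 in 2 libraries, which leaves fewer genes, 206 genes were lower at 1 h and 107 higher and 165 lower between the untreated libraries. The fatty acid synthesis median was −1.03 at 6 h and the inflammatory median 5.45 at 6 h and 4.08 at 24 h. Without transcripts under 200 bases 108 genes were higher between the untreated libraries.

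With rescaling, 274, 1256 and 1050 genes were lower at 1, 6 and 12 h, and 945 higher and 1012 lower at 24 h than at 6 h. The cholesterol median was 0.12, 0.10 and 0.46 at 1, 6 and 12 h (−0.06, −0.34 and 0.14), the fatty acid synthesis median −0.042, −0.28 and −0.16 (−0.21, −0.65 and −0.42), the LXR target median −0.074 and −0.14 at 1 and 6 h (−0.26 and −0.59) and the interferon median 5.64 and 6.21 at 6 and 12 h. These moves follow from the shift of all genes.

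With the other untreated library as control, the cholesterol median at 12 h changed sign to −0.18, Abca1 at 1 h reversed from 0.61 to −0.43 and Scd2 at 24 h from −0.23 to 0.71. List medians in this paragraph are plain ones, not taken relative to all genes. Whether the cholesterol list at 12 h stayed high relative to all genes with this control is not given here. The cholesterol median was −0.38 and −0.67 at 1 and 6 h, the fatty acid synthesis median −0.44, −0.68 and −0.25 at 1, 12 and 24 h, the LXR target median 0.15, 0.045 and −0.46 at 6, 12 and 24 h (−0.59, −0.66 and −0.12), the inflammatory median 3.23 at 24 h and the interferon median 5.53 at 6 h.

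The share of SREBP1 peaks that overlap LXR peaks was 27.2% as reported, 15.1% with at least 50% of each peak shared, 16.2% with centres within 100 bases and 21.9% with the higher-scoring part of each list, where fewer LXR peaks are left to overlap.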

Other observations

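The shares of peaks of highest score, the tests of the peaks at Pgk1 and Vdr, and the rescaled sets below were chosen only after the results were seen. Genes of glycolysis were higher after 24 h of KLA than in the untreated 24 h library. All 15 lay above 0, 7 were at least 2-fold higher, and the median of 0.94 lay 1.03 above that of all genes (percentile 99.94 of matched random lists). Hexokinase Hk2 was 3.60-fold higher (2.98 to 4.39), Pfkl 3.18-fold (2.54 to 4.02), the glucose transporter Slc2a1 2.19-fold (1.86 to 2.59) and Ldha 2.18-fold (1.98 to 2.40). The counts rest on the control. In the other untreated library Aldoa and Pkm, at 437 and 200 RPKM, stood above their 416 and 160 with KLA. Slc2a1 and Ldha, at 37.4 and 177 RPKM there, were less than 2-fold higher with KLA. Between the untreated libraries 14 of 15 glycolysis genes were lower in the 24 h one (median −0.21, percentile 9.31). Gapdh and Pgk1, which have processed pseudogenes, were at only 20.0 and 16.4 RPKM and are uncertain. At 6 h the list was at −0.52 (percentile 30.8), with Pfkl at 4.76 against 11.2 RPKM, and at 12 h at 0.32 (98.6). The TCA cycle list was near the other genes at 1, 6, 12 and 24 h (percentiles 38.6, 14.8, 37.2 and 60.0). Genes of fatty acid oxidation and storage were lower, with medians of −0.38 at 1 h (percentile 1.10), −1.16 at 6 h (8 of 15 at least 2-fold lower), −1.11 at 12 h (8 of 15) and −0.54 at 24 h (5 of 15), at percentiles 0.06, 0.02 and 1.13. At 24 h the fatty acid transporter Cd36 was 5.59-fold lower (5.35 to 5.84), the lipid chaperone Fabp4 9.72-fold (8.09 to 11.8) and the lipid droplet protein Plin2 2.90-fold lower (2.69 to 3.12), while Angptl4 was 2.71-fold higher (1.28 to 6.25). The oxidation genes Cpt1a, Acadvl and Acadl stood at ratios of 1.07 (0.887 to 1.29), 0.997 (0.747 to 1.33) and 0.918 (0.780 to 1.08). Hadha and Hadhb were 1.85-fold (1.53 to 2.23) and 2.73-fold lower (1.44 to 5.47). At 1 h Fabp4 was 2.21-fold higher (2.07 to 2.37).

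Macrophage identity genes had medians inside the central 95% at all 4 times (percentiles 51.7, 50.1, 16.4 and 22.0), but single members went far apart at 24 h. The Fc receptor Fcgr1 was 8.20-fold higher (6.69 to 10.2) and Emr1, the gene of F4/80, 4.79-fold (4.39 to 5.23), the integrin gene Itgam was 2.18-fold lower (1.94 to 2.45), and Csf1r was at 120 against 117 RPKM. Of 10 alternative activation genes 2 were at least 2-fold higher at 24 h and 3 lower (percentile 80.7, and 98.68, 78.6 and 3.32 at 1, 6 and 12 h), with the mannose receptor Mrc1 11.3-fold lower (9.07 to 14.3) and Il4ra 3.28-fold higher (2.59 to 4.20). Mrc1, at 5.98 RPKM with KLA, stood at 67.7 RPKM in the untreated 24 h library and 36.6 in the other. Against that other library Retnla (10.6 against 26.6 RPKM) and Folr2 (17.3 against 38.6) were also more than 2-fold lower. The cell cycle list (17 of 25 members tested) lay at percentiles 69.6, 55.9, 49.8 and 21.1. Of the lists of other cell types, 3 of 10 neutrophil markers were tested (median 1.35 at 24 h, percentile 98.68, or 1.17 at the bound), 6 of 12 lymphocyte markers (−0.12, 52.1), 9 of 10 stromal and mesothelial markers (−0.23, 34.3), 2 of 8 dendritic cell markers and 0 of 10 markers of mast cells and eosinophils. The neutrophil median of 1.35 is the value of S100a8 alone and does not describe a list. The other 2 were Camp, with 7 reads with KLA and 0 without, and Ltf, with 0 and 1. The neutrophil gene Mpo was listed at 0 in all 6 libraries, and S100a9 and Elane had 1 read each in the untreated library for 1 to 12 h (0.872 and 0.493 RPKM) and none in the others. Of the dendritic markers Ccr7 was at 8.90 against 0.783 RPKM at 24 h and Itgax at 63.5 against 181, and both are also expressed by macrophages. The collagen gene Col1a1 was 2.10-fold higher at 24 h (1.75 to 2.54) and Col3a1 1.52-fold lower. No SREBP1 peak lay within 10 kb of any of 9 stromal genes (56.2% in random lists, percentile 0.02). LXR peaks were few there too, by 2 of the 9 (73.4% in random lists matched on untreated expression, percentile 0.09). Of the 100 LXR peaks of highest score 84% (75.3 to 90.6) lay within 1 kb of a start site, against 39.4% of the 500 highest and 17.1% of all. Of the 100 highest SREBP1 peaks 43 lay there and 72 overlapped an LXR peak.

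Genes at least 2-fold higher after 6 h and 24 h of KLA had fewer SREBP1 peaks than genes of the same mean expression. A candidate explanation is that these genes are weakly expressed in cells without KLA, the state that the label of the SREBP1 sample gives. Which samples its combined tag directory holds is not known. Their median was 4.33 and 4.49 RPKM in the untreated libraries against 8.15 and 8.45 for all genes, and with sets matched on untreated expression the shares lay at percentiles 19.6 and 13.1, inside the central 95%. The lower share against sets of the same mean expression did not rest on low-scoring peaks alone. The higher-scoring part of the peaks gave 39.6% and 40.6% against 49.8% and 49.9% in random sets (percentile 0 at both times). Nor did it rest on the scaling of the RPKM values (56.5% against 62.7% and 53.4% against 63.0%, percentile 0 at both times). These 2 tests were not made with sets matched on untreated expression, where the shares lay inside the central 95%, so they cannot show a shortage of peaks beyond the matching.

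The 7 SREBP1 peaks of highest score, at Pgk1 and inside Vdr, stand apart from the rest. Extra copies of these regions in the genome of the cells are argued against by the input, with a median of 0.5 tags in these peaks (highest 6) and 1 over all peaks. Regions that collect tags with any antibody are argued against for the 6 Vdr peaks alone, since none of them overlaps an LXR peak. LXR peaks with scores of up to 28 did lie elsewhere inside Vdr. The 1 of the 7 that overlaps an LXR peak is that at Pgk1, the highest of all, and there this explanation stays open. An evenly covered stretch of added DNA such as a whole clone stays open, because peaks were called only at 4-fold or more over the surrounding bases, so that the median of 24.4-fold in the 6 Vdr peaks decides nothing. Short pieces of added DNA such as a cDNA construct or PCR products stay open too, since 0 of the 6 flanking peaks were as high, and neither can be told apart from binding of SREBP1, because no control precipitation with another antibody from the same chromatin was analysed here. No biological explanation was tested.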
